A study of Mus musculus with 28 samples.

How the data were processed

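Total RNA of dendritic cells sorted from mouse kidney was amplified and measured on 28 Affymetrix arrays, in 8 groups given by the labels: homeostatic cortex and medulla of C57BL/6 and of BALB/c mice (4 arrays each), and donor and host cells of graft cortex and graft medulla (3 arrays each). The deposited values are log2 array signal that the authors made by RMA (background correction, quantile normalization and summary of the probes of each probeset) with the oligo package, per the submitters' processing notes; versions are not given in the sources used here. The values were used as given. The number of arrays limits the precision.

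The table holds 22549 probesets. Of these, 20646 have 1 gene symbol and were used, and 551 with several symbols and 1352 with no listed symbol were left out. They cover 19272 gene symbols, of which 810 have more than 1 probeset and 19227 match an identifier of the mouse gene table. For each gene the probeset with the highest mean over the 28 arrays was kept. A gene was tested when its value lay above the 40th percentile of its array in at least 3 arrays, whatever their group, which left 14346 genes.

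Groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with 1 mean per group over all 28 arrays (20 residual degrees of freedom) and moderated statistics with 1 spread shared by all groups. Tests were 2-sided, p-values were adjusted by the method of Benjamini and Hochberg over the genes tested in each comparison, and a difference passed when its adjusted p was under 0.05. There were 12 comparisons of groups: medulla against cortex within each of the 4 kinds of cells, BALB/c against C57BL/6, donor against homeostatic BALB/c, host against homeostatic C57BL/6, and donor against host, each of the last 4 in cortex and in medulla. A further 5 comparisons tested differences of differences by interaction contrasts: the medulla-cortex difference of BALB/c minus C57BL/6, of donor minus BALB/c and of host minus C57BL/6 cells, and the donor-host difference minus the strain difference in cortex and in medulla. Overlaps were set against the product of the shares of genes called.

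The labels give mouse numbers that join cortex and medulla, and donor and host cells, of 11 mice. As a check of this pairing, residuals from the group means were correlated between arrays: arrays of the same mouse had a mean correlation of 0.155 (donor regions), 0.106 (host regions), 0.22 (donor and host cortex) and 0.171 (donor and host medulla), each above that of arrays of other mice, but -0.003 in C57BL/6 and -0.006 in BALB/c kidneys. The model has no term for mouse, and mouse as a block was an alternative; the consensus correlation of arrays of 1 mouse was 0.134.

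Gene lists were fixed before the data were examined, as were the comparisons, the filter, the rule for named genes and the alternatives. Of 33 lists, the 31 with at least 3 members among the genes tested were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison. Camera compares a list with all other genes; the alternatives were an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction. The lists cover osmotic stress and NFAT5 targets, hypoxia and glycolysis, the type I interferon and interferon-gamma responses, MHC class I and class II presentation, dendritic cell maturation, inflammatory cytokines and chemokines, chemokine receptors, immediate early and dissociation stress genes, cell cycle, complement, the unfolded protein response, pattern recognition receptors, phagocytic and scavenger receptors, and heme and iron handling. Marker lists cover type 1, type 2, plasmacytoid and pan dendritic cells, resident macrophages, monocytes, neutrophils, B, T and natural killer cells, the proximal tubule, the loop of Henle and distal tubule, the collecting duct, endothelium, fibroblasts and pericytes, erythroid cells, and sex-linked genes. Lists share members, such as the C1q genes in the macrophage and complement lists. A list of leukocyte-wide and a list of epithelium-wide genes were written after the first results had been seen, and before their own values were read.

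Genes are named by a fixed rule. Of the genes that passed and whose groups do not overlap, the 8 highest and 8 lowest differences of each comparison were eligible, or 4 and 4 by adjusted p alone for interaction contrasts, leaving out predicted genes, pseudogenes and olfactory or vomeronasal receptors. Of each list called by camera up to 4 members with the smallest adjusted p were eligible, and of each other list up to 2 that passed. The sort markers Ptprc, Itgax and H2-Ab1 were eligible in every group, and names were left out for length.

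The alternatives were mouse as a random block, mouse as a fixed block in a fit of the groups compared where these share mice, no filter on dim genes, a strict filter (mean above the median of all probesets), a second quantile normalization, a variance trend with robust estimates, a fit of only the groups compared, the mean of a gene's probesets, and leaving out each array of the groups compared. Array weights, and leaving out BALB/c medulla replicate 1 in every comparison, were added after seeing the data.

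The model was tested on 14346 simulated genes with the same group sizes, 50 changed per size of change. For C57BL/6 medulla against cortex it recovered 46, 84, 96 and 100% of genes changed by 1, 2, 3 and 4 log2 units. It was 42, 80, 86 and 92% for donor against host medulla, and 28, 62, 88 and 88% for the strain difference of the regions. With no change the highest count over the 17 contrasts was 0, and of simulated lists 3 of 3 raised and 1 of 27 unchanged lists were called.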

Results

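The data are gene expression values from 28 arrays of renal dendritic cells of the mouse, antigen-presenting cells that were sorted by the surface proteins CD45, CD11c and MHC class II. Cells came from the cortex (outer kidney) and the medulla (inner kidney) of healthy kidneys, called homeostatic, and of kidney allografts 3 days after transplantation. Homeostatic cells were taken from C57BL/6 and from BALB/c mice, with 4 arrays each for cortex and medulla in each strain. In the grafts, donor cells carried CD45.2 and are labelled BALB/c, and host cells carried CD45.1, a variant of the same protein, and are labelled C57BL/6. Host and donor cells were sorted from the same grafts, with 3 arrays each for cortex and medulla of both. The 28 arrays came from 11 mouse numbers. Levels are log2 array signal, given as mean ± SD with n = 4 for homeostatic groups and n = 3 for graft groups, and differences are log2 differences ± SE from limma. A difference counted as passing when its adjusted p over 14346 genes was under 0.05; counts over the list alone adjust within the list. Where the median of all genes moved by 0.1 or more, the medians of lists given with counts of members are followed by those relative to it in parentheses. Counts of genes and lists that moved by over 1.5 times are given with the setting: mouse as a random or fixed block, no or a strict filter on dim genes, renormalized (a second quantile normalization), a robust variance trend, the groups compared fitted alone, array weights, chosen after seeing the data, or for lists fry, which compares a list with no other genes.

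Transcripts of the sorted proteins were high in most groups and fell short in the graft medulla. Ptprc, which encodes CD45, stood at 12.79 ± 0.04 in homeostatic C57BL/6 medulla, 11.23 ± 0.23 in donor medulla and 9.67 ± 1.09 in host medulla. Itgax, which encodes CD11c, was at 11.32 ± 0.31 and 11.09 ± 0.21 in cortex and medulla of C57BL/6, at 10.46 ± 0.93 and 8.43 ± 0.97 of BALB/c, at 10.02 ± 0.78 and 7.38 ± 0.19 of donor cells, and at 9.15 ± 1.46 and 7.66 ± 0.45 of host cells. H2-Ab1, an MHC class II chain, was at 13.24 ± 0.07 in homeostatic C57BL/6 medulla and 9.54 ± 1.19 in host medulla. A list of 22 leukocyte-wide genes, such as Laptm5 and Cd53, averaged 11.11 ± 0.07 in homeostatic C57BL/6 medulla, 10.55 ± 0.13 in BALB/c medulla, 9.54 ± 0.71 in donor medulla and 8.53 ± 0.58 in host medulla. In the cortex the same list averaged 10.93 ± 0.06 in C57BL/6, 10.66 ± 0.27 in BALB/c, 9.91 ± 0.44 in donor and 10.05 ± 0.90 in host cells. A list of 14 epithelium-wide genes went the other way, from 7.99 ± 0.10 in homeostatic C57BL/6 medulla to 9.95 ± 0.20 in donor and 10.27 ± 0.16 in host medulla. Both lists were written after the first results had been seen. Homeostatic BALB/c medulla replicate 1 stood apart, with a mean correlation of 0.766 with its own group, where all other arrays lay between 0.832 and 0.947. The SD over all probesets averaged between 1.63 and 1.74 in 6 groups and was lower in both homeostatic BALB/c groups.

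**Figure D1:**
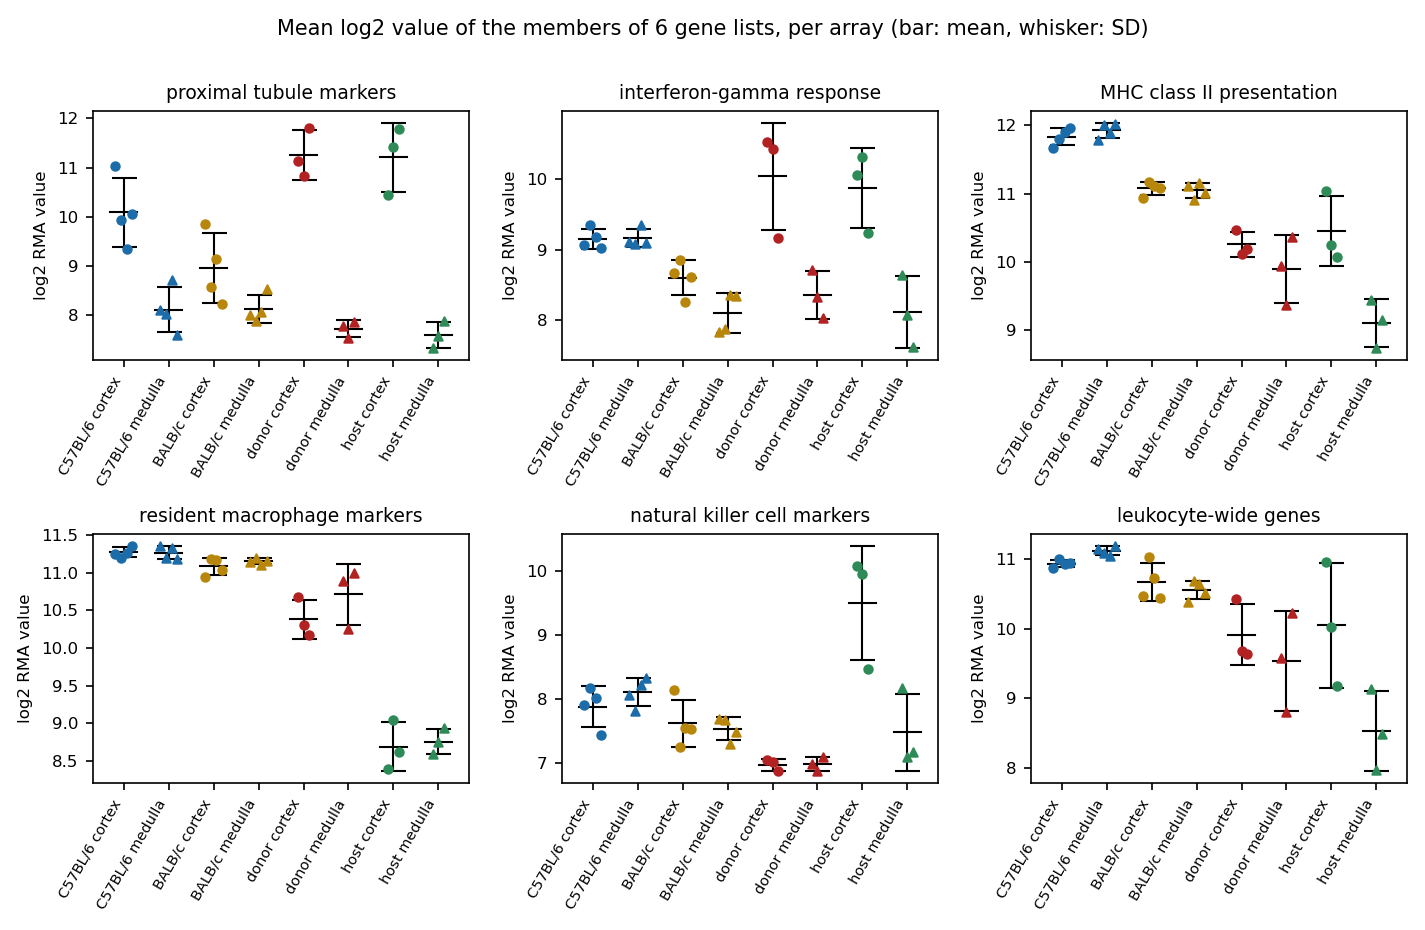
Mean log2 level of 6 gene lists (vertical axes) on each of the 28 arrays, in the 8 groups (horizontal axis); points are arrays, bars are group means and whiskers are SD. Host cells hold the lowest levels of the resident macrophage list in both regions, and donor and host cortex hold the highest mean levels of the proximal tubule and interferon-gamma lists.

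The first question was how dendritic cells of the medulla differ from those of the cortex in the healthy kidney. In C57BL/6 cells the genes that passed were almost all lower in the medulla, and many were genes of kidney tubules. Whether the sorted cells or tubule RNA in the samples gave these transcripts was not tested in homeostatic kidneys. Cyp2e1, a cytochrome P450 of the proximal tubule, was at 7.09 ± 0.68 against 12.55 ± 0.39, difference -5.46 ± 0.67. S100g and Calb1, calcium-binding proteins of the distal tubule, differed by -4.27 ± 0.43 and -4.74 ± 0.62, and Lrp2, the endocytic receptor megalin, by -3.48 ± 0.52. Acsm2, Slc27a2 and Fbp1, metabolic genes of the proximal tubule, fell by 3.95 ± 0.49, 3.85 ± 0.76 and 2.99 ± 0.58. Proximal tubule markers (4 of 16 lower, 13 over the list alone, median -1.54, adjusted p = 1.1e-34) fell. The set test also placed lower loop of Henle and distal tubule markers (1 of 11 lower, 1 over the list alone, median -1.07, adjusted p = 6.7e-06) and collecting duct markers (1 of 12 lower, 1 over the list alone, median -0.20, adjusted p = 0.0014), but adjusted p = 0.24 and 0.27 with an estimated correlation. Ndrg1, a hypoxia-induced gene, fell by 2.28 ± 0.45, but the hypoxia and glycolysis list was not called. Among immune lists, the set test placed higher in the medulla markers of type 2 conventional dendritic cells (0 of 7 passing, 2 over the list alone, median 0.60, adjusted p = 0.004) and dendritic cell maturation genes (0 of 17 passing, 1 over the list alone, median 0.16, adjusted p = 0.0028), but adjusted p = 0.24 and 0.094 with an estimated correlation.

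In C57BL/6 cells, 22 of 14346 genes passed, 1 higher and 21 lower; 8 of 31 lists were called (1 by fry), 1 also with an estimated correlation. The count became 6 without medulla replicate 4 to 55 without cortex replicate 3 over the 8 arrays that moved it. Slc27a2 and Fbp1 lost their calls without any one of 6 arrays, Ndrg1 without any one of 5 arrays. Other settings gave 38 (random block), 1 (fixed block), 5 (groups alone) and 100 (array weights).

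In homeostatic BALB/c cells 10 genes passed between medulla and cortex, 3 higher and 7 lower. C57BL/6 cells shared 0 (0.01 of those lower if independent), and 90.5% of their lower genes had the same sign. Cd300ld, a receptor of myeloid cells, was at 8.80 ± 0.42 against 11.40 ± 0.36, difference -2.59 ± 0.37. Pilra, an inhibitory receptor of myeloid cells, and Mapk14, the kinase p38 alpha, fell by 2.90 ± 0.53 and 2.14 ± 0.38. Lsm10, a small nuclear ribonucleoprotein component, rose by 3.73 ± 0.57, and Snrpa1, a spliceosome protein, fell by 3.34 ± 0.44. The set test placed lower proximal tubule markers (0 of 16 passing, 1 higher and 3 lower over the list alone, median -0.60, adjusted p = 1.5e-04), type I interferon response genes (0 of 19 passing, 0 over the list alone, median -0.63, adjusted p = 1.4e-04) and interferon-gamma response genes (0 of 16 passing, 0 over the list alone, median -0.45, adjusted p = 0.0084), but adjusted p = 0.52, 0.44 and 0.52 with an estimated correlation. It placed higher osmotic stress genes, targets of the transcription factor NFAT5 (0 of 8 passing, 2 over the list alone, median 0.59, adjusted p = 0.012) and immediate early genes (0 of 20 passing, 0 over the list alone, median 0.29, adjusted p = 0.0084), but adjusted p = 0.44 and 0.52 with an estimated correlation. 5 of the 31 lists were called (0 by fry), and 0 with an estimated correlation. The gene count became 21, 29 and 25 without medulla replicates 1, 2 and 3. Pilra lost the call without cortex replicates 1 or 4 or medulla replicate 4, Mapk14 without cortex replicates 3 or 4 or medulla replicate 1. Other settings gave 40 (random block), 16 (strict filter), 40 (renormalized, 21 higher and 19 lower), 1 (groups alone) and 0 by limma (fixed block) with 655 at an unadjusted p under 0.05.

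The regional difference of BALB/c cells was set against that of C57BL/6 cells. It differed for 6 genes, 1 higher and 5 lower, among them Lsm10 (4.55 ± 0.80), Snrpa1 (-3.81 ± 0.62) and Cd300ld (-2.87 ± 0.52). The set test placed higher proximal tubule markers (0 of 16 passing, 4 over the list alone, median 1.33, adjusted p = 4.9e-07) and loop of Henle and distal tubule markers (0 of 11 passing, 3 over the list alone, median 1.90, adjusted p = 6.7e-07), but adjusted p = 0.34 and 0.31 with an estimated correlation. It placed lower dendritic cell maturation genes (0 of 17 passing, 2 over the list alone, median -0.28, adjusted p = 6.6e-04) and type 2 conventional dendritic cell markers (0 of 7 passing, 2 over the list alone, median -0.75, adjusted p = 0.012), but adjusted p = 0.063 and 0.38 with an estimated correlation. 7 lists were called (0 by fry, 4 without BALB/c medulla replicate 1), and 0 with an estimated correlation. Leaving out any of these single replicates left 0 genes in limma, with 485 to 736 at an unadjusted p under 0.05, namely C57BL/6 cortex 1, C57BL/6 medulla 1, 2 and 4, BALB/c medulla 1 and 4 and BALB/c cortex 2 and 4. The count was 3 without C57BL/6 cortex 3, 1 without C57BL/6 cortex 4, 11 without BALB/c cortex 1 and 2 without BALB/c medulla 2. Lsm10 and Cd300ld lost their calls without any one of 12 arrays, Snrpa1 without any one of 10 arrays. Other settings gave 3 (groups alone) and 0 by limma (fixed block, no filter and robust trend) with 797, 768 and 611 at an unadjusted p under 0.05.

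The same regional question was asked of donor cells that had stayed in the graft. Donor cells of the medulla held far less of the proximal tubule transcripts and of the interferon-gamma response than donor cells of the cortex. Cubn, the endocytic receptor cubilin, was at 6.37 ± 0.04 against 11.19 ± 0.07, difference -4.82 ± 0.39, and Lrp2 differed by -5.18 ± 0.60. Cxcl9, a chemokine induced by interferon-gamma, was at 8.52 ± 0.39 against 11.43 ± 1.23, difference -2.91 ± 0.57, and Cxcl10, of the same kind, differed by -3.24 ± 0.64. Cd274, which encodes the checkpoint ligand PD-L1, fell by 2.42 ± 0.31, and Cfb, factor B of complement, by 3.53 ± 0.45. Genes higher in the medulla included Npy (4.35 ± 0.49) and Angpt2 (3.99 ± 0.42), which encode a neuropeptide and a vascular growth factor. The median difference of all genes was 0.11, that of leukocyte-wide genes -0.53 and that of epithelium-wide genes 0.76. Interferon-gamma response genes (7 of 16 lower, 10 over the list alone, median -1.94 (-2.05), adjusted p = 1.7e-12) fell. Proximal tubule markers (14 of 16 lower, 1 higher and 15 lower over the list alone, median -4.25 (-4.36), adjusted p = 4.2e-29) fell. Lower by the set test were cell cycle genes (1 of 25 lower, 2 over the list alone, median -0.76 (-0.87), adjusted p = 1.6e-04), MHC class I presentation genes (1 of 11 lower, 2 over the list alone, median -0.31 (-0.42), adjusted p = 0.0044) and complement genes (2 of 9 lower, 3 over the list alone, median -0.16 (-0.27), adjusted p = 0.0044), but adjusted p = 0.39, 0.17 and 0.29 with an estimated correlation.

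In the same donor cells, the set test placed higher in the medulla osmotic stress genes (0 of 8 passing, 2 over the list alone, median 0.94 (0.83), adjusted p = 0.043), but adjusted p = 0.38 with an estimated correlation. That call ended with mouse as a block, at adjusted p = 0.053. Single genes of other lists that fell were Cd36 (-4.16 ± 0.45), Ccr2 (-2.25 ± 0.50), Dpp4 (-2.79 ± 0.54) and Itgax (-2.64 ± 0.60), and Mrc1 (1.55 ± 0.38) and Apoe (1.15 ± 0.23), macrophage genes, rose. In all, 365 genes passed, 90 higher and 275 lower; 10 lists were called (6 by fry), 2 also with an estimated correlation. Ccr2 lost the call without donor cortex replicate 1 or donor medulla replicate 2, Itgax without donor cortex replicates 1 or 3 or donor medulla replicate 1, Mrc1 without donor cortex replicate 3 or donor medulla replicates 1 or 3. Other settings gave 69 (fixed block), 234 (strict filter), 188 (groups alone) and 1796 (array weights, 1121 higher and 675 lower).

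The regional difference of donor cells differed from that of homeostatic BALB/c cells for 65 genes, 8 higher and 57 lower. This difference of differences was -4.61 ± 0.51 for Cubn, -4.37 ± 0.79 for Lrp2, -2.58 ± 0.41 for Cd274, 3.87 ± 0.55 for Angpt2 and 2.49 ± 0.28 for Slc14a2, a urea transporter of the medulla. Proximal tubule markers (5 of 16 lower, 15 over the list alone, median -2.73, adjusted p = 1.8e-20) fell more in donor cells. Lower by the set test were interferon-gamma response genes (1 of 16 lower, 7 over the list alone, median -0.86, adjusted p = 3.1e-06) and cell cycle genes (0 of 25 passing, 0 over the list alone, median -0.82, adjusted p = 3.8e-05), but adjusted p = 0.16 and 0.57 with an estimated correlation. 5 lists were called (1 by fry, 3 renormalized), 1 of them also with an estimated correlation. The gene count became 111 without BALB/c cortex replicate 1. Other settings gave 105 (random block), 27 (fixed block) and 30 (strict filter).

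Host cells, which had entered the graft from the recipient, were compared between medulla and cortex in the same way. Host cells of the medulla were lower in the interferon-gamma response, in MHC class II presentation, in natural killer transcripts and in proximal tubule transcripts. Cxcl9 was at 7.00 ± 0.14 against 10.57 ± 0.84, difference -3.57 ± 0.57. Cd74, the invariant chain of MHC class II, was at 8.83 ± 0.63 against 10.93 ± 0.72, difference -2.10 ± 0.35, and Ctss, the protease that trims it, differed by -2.27 ± 0.37. Gzmb, a granzyme of cytotoxic lymphocytes, and Ncr1, an activating receptor of natural killer cells, differed by -3.11 ± 0.54 and -2.45 ± 0.47. Ptprc differed by -2.04 ± 0.43 and H2-Ab1 by -2.21 ± 0.43. The median difference of all genes was 0.10, that of leukocyte-wide genes -1.35 with 8 of 22 lower, and that of epithelium-wide genes 1.13 with 5 of 14 higher. Falls that held with an estimated correlation were those of interferon-gamma response genes (7 of 16 lower, 12 over the list alone, median -1.90 (-2.01), adjusted p = 3.6e-13) and MHC class II genes (7 of 10 lower, 7 over the list alone, median -1.37 (-1.48), adjusted p = 4.0e-11). So did those of natural killer markers (3 of 6 lower, 5 over the list alone, median -2.37 (-2.47), adjusted p = 8.0e-07), MHC class I genes (3 of 11 lower, 4 over the list alone, median -0.45 (-0.56), adjusted p = 5.3e-05) and proximal tubule markers (1 higher and 14 lower of 16, 1 higher and 15 lower over the list alone, median -4.09 (-4.20), adjusted p = 1.3e-30).

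The set test also placed lower in host medulla pan dendritic cell markers (2 of 9 lower, 5 over the list alone, median -1.48 (-1.59), adjusted p = 5.3e-05), monocyte markers (1 of 9 lower, 1 higher and 4 lower over the list alone, median -1.15 (-1.26), adjusted p = 0.0023) and plasmacytoid dendritic cell markers (1 of 7 lower, 4 over the list alone, median -1.02 (-1.12), adjusted p = 5.3e-05), but adjusted p = 0.076, 0.064 and 0.1 with an estimated correlation. Ccr2, the receptor by which monocytes leave the marrow, fell by 3.09 ± 0.50. Complement genes (1 higher and 2 lower of 9, 1 higher and 3 lower over the list alone, median -0.04 (-0.14), adjusted p = 0.049) were on the lower side, but adjusted p = 0.34 with an estimated correlation. C1qc, a chain of complement C1q, rose by 1.06 ± 0.27 while Cfb fell by 3.87 ± 0.45. Osmotic stress genes (1 of 8 higher, 2 over the list alone, median 1.06 (0.96), adjusted p = 0.045) were on the higher side, but adjusted p = 0.19 with an estimated correlation. Slc6a12, the betaine transporter, rose by 2.12 ± 0.37. The calls of complement and osmotic stress genes ended with mouse as a block, at adjusted p = 0.055 and 0.052. In all, 615 genes passed, 267 higher and 348 lower; 16 lists were called, 5 also with an estimated correlation. C1qc lost the call without host cortex replicates 1 or 2 or host medulla replicates 1 or 2. Other settings gave 64 (fixed block), 398 (strict filter) and 135 (groups alone).

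Donor and host cells, on different arrays from the same grafts, shared 173 of the genes lower in the medulla and 46 of those higher, against 6.67 and 1.68 if the calls were independent. The regional difference of host cells differed from that of homeostatic C57BL/6 cells for 129 genes, 72 higher and 57 lower. It was -4.28 ± 0.76 for Cxcl9, -2.16 ± 0.47 for Cd74, -3.20 ± 0.71 for Gzmb, -3.04 ± 0.67 for Ccr2, -3.72 ± 0.59 for the scavenger receptor Cd36 and -5.18 ± 0.34 for the fatty acid-binding protein Fabp7. Lists that fell more in host cells were interferon-gamma response genes (1 of 16 lower, 7 over the list alone, median -1.71, adjusted p = 2.6e-12), MHC class II genes (2 of 10 lower, 7 over the list alone, median -1.47, adjusted p = 5.5e-12) and natural killer markers (1 of 6 lower, 4 over the list alone, median -2.04, adjusted p = 3.4e-07). So were MHC class I genes (median -0.55, adjusted p = 2.1e-06), maturation genes (median -0.53, adjusted p = 2.4e-05), pan dendritic cell markers (median -1.27, adjusted p = 1.1e-05) and monocyte markers (median -2.36, adjusted p = 1.7e-04). 16 lists were called (9 by fry), 9 of them with an estimated correlation, and leukocyte-wide genes had a median of -1.48. The gene count became 85 without host cortex replicate 2. Cd74 lost the call without host cortex replicates 1 or 2 or host medulla replicate 2, Gzmb without any one of 9 arrays, Ccr2 without C57BL/6 medulla replicates 2 or 4, host cortex replicate 1 or host medulla replicate 3. Other settings gave 84 (fixed block, 41 higher and 43 lower), 80 (strict filter) and 378 (array weights).

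Homeostatic strains were compared because donor and host cells differ in strain. In the cortex, BALB/c signal was lower than C57BL/6 signal for some MHC class II genes, and single interferon-induced genes went both ways. Sequence differences under the probes were not tested. H2-Ob, which restrains peptide loading of class II, was at 8.34 ± 0.40 against 11.17 ± 0.15, difference -2.83 ± 0.39, and H2-Ab1 differed by -1.23 ± 0.37. Iigp1, an interferon-induced GTPase, was at 7.27 ± 0.50 against 10.05 ± 0.19, difference -2.78 ± 0.52, and Ifi202b, an interferon-induced DNA sensor, rose by 3.63 ± 0.54. Slamf7, a surface protein of leukocytes, fell by 3.29 ± 0.42, and C5ar1, the receptor of complement fragment C5a, by 2.22 ± 0.43. Lower by the set test were MHC class II genes (3 of 10 lower, 4 over the list alone, median -0.58, adjusted p = 4.0e-04), proximal tubule markers (4 of 16 lower, 5 over the list alone, median -1.07, adjusted p = 1.5e-05) and interferon-gamma response genes (1 of 16 lower, 1 over the list alone, median -0.39, adjusted p = 0.027), but adjusted p = 0.47 each with an estimated correlation. It placed higher fibroblast and pericyte markers (median 0.34, adjusted p = 0.033), but adjusted p = 0.47 with an estimated correlation. In all, 1421 genes passed, 1142 higher and 279 lower, at 2-fold or more 63 and 237; 6 lists were called (3 by fry, 13 no filter), 0 also with an estimated correlation. The count became 504 without BALB/c replicate 4 to 601 without C57BL/6 replicate 2 over the 4 arrays that moved it. H2-Ab1 lost the call without any one of 8 arrays. Other settings gave 3897 (no filter), 351 (strict filter), 835 (renormalized, 653 higher and 182 lower), 661 (groups alone) and 2702 (array weights).

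In the medulla, BALB/c signal was lower for some dendritic cell and MHC class II genes. Itgax was at 8.43 ± 0.97 against 11.09 ± 0.21, difference -2.66 ± 0.52, and Flt3, the receptor of a growth factor of dendritic cells, differed by -2.23 ± 0.54. Klrd1, which encodes CD94, was at 7.04 ± 0.57 against 11.42 ± 0.47, difference -4.38 ± 0.87. H2-Ob, H2-Ab1 and Ciita, the master regulator of class II, differed by -2.96 ± 0.39, -1.37 ± 0.37 and -1.12 ± 0.27. All genes had a median difference of 0.17, leukocyte-wide genes of -0.48 and epithelium-wide genes of 0.58. The set test placed lower MHC class II genes (5 of 10 lower, 6 over the list alone, median -0.66 (-0.83), adjusted p = 1.9e-05), interferon-gamma response genes (4 of 16 lower, 9 over the list alone, median -1.12 (-1.29), adjusted p = 1.9e-05) and type 2 conventional dendritic cell markers (2 of 7 lower, 4 over the list alone, median -1.34 (-1.51), adjusted p = 8.4e-05), but adjusted p = 0.13 each with an estimated correlation. It also placed lower type I interferon response genes (1 of 19 lower, 0 over the list alone, median -0.88 (-1.05), adjusted p = 1.9e-05) and pan dendritic cell markers (3 of 9 lower, 4 over the list alone, median -0.29 (-0.46), adjusted p = 0.0012), but adjusted p = 0.13 and 0.17 with an estimated correlation. In all, 1307 genes passed, 930 higher and 377 lower, at 2-fold or more 63 and 333; 13 lists were called (7 renormalized), 0 also with an estimated correlation. Cortex and medulla shared 520 of the genes higher in BALB/c and 65 of those lower, against 74.0 and 7.33 if independent. The count became 230 without BALB/c replicate 1 to 2353 without BALB/c replicate 3 over the 7 arrays that moved it. Flt3 lost the call without BALB/c replicates 1 or 4 or C57BL/6 replicates 2 or 3, H2-Ab1 without any one of 6 arrays, Ciita without BALB/c replicate 1 or C57BL/6 replicates 3 or 4. Other settings gave 3485 (no filter), 372 (strict filter, 153 higher and 219 lower) and 110 (groups alone, 25 higher and 85 lower).

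Donor cells of the graft were set against homeostatic BALB/c cells to see what differs in the cells that came with the kidney. By the set test, donor cells of the cortex were higher in interferon-gamma response, proximal tubule and cell cycle genes, and lower in inflammatory cytokines and MHC class II genes, but 0 of the 12 lists called (6 no filter, 5 array weights) held with an estimated correlation. Iigp1 was at 12.32 ± 0.62 against 7.27 ± 0.50, difference 5.05 ± 0.56, Cxcl10 at 11.68 ± 0.43 against 8.31 ± 0.81, difference 3.37 ± 0.60, and Cd274 differed by 1.82 ± 0.29. Ccl3, a chemokine of myeloid cells, was at 9.30 ± 1.23 against 12.72 ± 0.39, difference -3.43 ± 0.75, and Il1b, which encodes interleukin-1 beta, differed by -2.15 ± 0.51. Cd74 and Ciita fell by 1.38 ± 0.33 and 1.02 ± 0.29. Mki67 and Cdk1, genes of dividing cells, rose by 1.71 ± 0.43 and 1.78 ± 0.57. Lrp2 rose by 4.05 ± 0.56 and Lcn2, which injured tubules and neutrophils make, by 2.92 ± 0.32. All genes had a median difference of -0.13, leukocyte-wide genes of -0.64 and epithelium-wide genes of 0.56. The set test placed higher interferon-gamma response genes (9 higher and 1 lower of 16, 9 higher and 1 lower over the list alone, median 1.47 (1.60), adjusted p = 6.8e-05), proximal tubule markers (10 of 16 higher, 12 over the list alone, median 2.03 (2.16), adjusted p = 3.7e-10) and cell cycle genes (4 of 25 higher, 3 over the list alone, median 0.85 (0.98), adjusted p = 6.8e-05), but adjusted p = 0.23, 0.23 and 0.4 with an estimated correlation.

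In donor cortex the set test placed lower inflammatory cytokines and chemokines (8 of 19 lower, 8 over the list alone, median -0.59 (-0.46), adjusted p = 0.027), MHC class II genes (4 of 10 lower, 5 over the list alone, median -0.82 (-0.69), adjusted p = 0.017) and resident macrophage markers (6 of 16 lower, 1 higher and 7 lower over the list alone, median -0.73 (-0.60), adjusted p = 0.028), but adjusted p = 0.4 each with an estimated correlation. Ms4a7 and Cx3cr1, macrophage genes, fell by 3.14 ± 0.45 and 1.26 ± 0.29. Higher were also hypoxia and glycolysis genes (median 0.61, adjusted p = 0.013) and loop of Henle and distal tubule markers (median 1.55, adjusted p = 0.0077), but adjusted p = 0.23 and 0.4 with an estimated correlation. In all, 3449 genes passed, 1135 higher and 2314 lower, at 2-fold or more 988 and 212. The BALB/c arrays spanned the narrower range. The count became 1765 and 1500 without donor cortex replicates 1 and 2 and 2266 without BALB/c cortex replicate 4. Il1b and Cd74 lost their calls without donor cortex replicate 2, Ciita without BALB/c cortex replicate 4 or donor cortex replicate 2, Mki67 without donor cortex replicate 1, Cdk1 without BALB/c cortex replicates 3 or 4 or donor cortex replicates 1 or 3. Other settings gave 6427 (no filter), 1669 (strict filter), 773 (groups alone, 559 higher and 214 lower) and 5650 (array weights).

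In the medulla, donor cells were lower in inflammatory cytokines and MHC class II genes than homeostatic BALB/c cells by the set test, but 0 of the 15 lists called held with an estimated correlation. Ccl3 was at 9.17 ± 2.77 against 12.86 ± 0.12, difference -3.69 ± 0.75, and Il1b at 9.90 ± 1.29 against 12.30 ± 0.39, difference -2.40 ± 0.51. Cd74 fell by 1.59 ± 0.33, Ifi30, a reductase of the class II pathway, by 2.49 ± 0.39, and the costimulator Cd86 by 2.57 ± 0.55. Cd36 and Clec7a, the receptor of fungal glucans, fell by 2.73 ± 0.42 and 2.34 ± 0.34. Lcn2, Angpt2 and Iigp1 rose by 3.46 ± 0.32, 3.60 ± 0.39 and 2.51 ± 0.56. All genes had a median difference of -0.11, leukocyte-wide genes of -0.86 and epithelium-wide genes of 1.42. The set test placed lower MHC class II genes (3 of 10 lower, 7 over the list alone, median -1.03 (-0.92), adjusted p = 9.1e-06), inflammatory cytokines and chemokines (5 of 19 lower, 5 over the list alone, median -0.50 (-0.40), adjusted p = 0.0029) and pattern recognition receptors (2 of 14 lower, 3 over the list alone, median -0.76 (-0.65), adjusted p = 0.0034), but adjusted p = 0.16, 0.16 and 0.17 with an estimated correlation. It placed higher loop of Henle and distal tubule markers (median 1.20, adjusted p = 0.0029), osmotic stress genes (median 0.83, adjusted p = 0.016) and hypoxia and glycolysis genes (median 0.46, adjusted p = 0.0091), but adjusted p = 0.29, 0.22 and 0.16 with an estimated correlation.

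In donor medulla, 456 genes passed, 248 higher and 208 lower, at 2-fold or more 234 and 63. A second quantile normalization gave 253 higher and 323 lower genes. Cortex and medulla shared 106 of the genes higher and 163 of those lower in donor cells, against 19.6 and 33.5 if independent. The count became 60 without donor medulla replicate 2 to 1087 without BALB/c medulla replicate 3 over the 5 arrays that moved it, with 151 without BALB/c medulla replicate 1. Ccl3, Il1b and Cd86 lost their calls without donor medulla replicates 1 or 2, Cd74 without donor medulla replicate 2, Iigp1 without BALB/c medulla replicate 1 or donor medulla replicates 1 or 2. Other settings gave 997 (no filter, 300 higher and 697 lower) and 4 (groups alone).

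**Figure D2:**
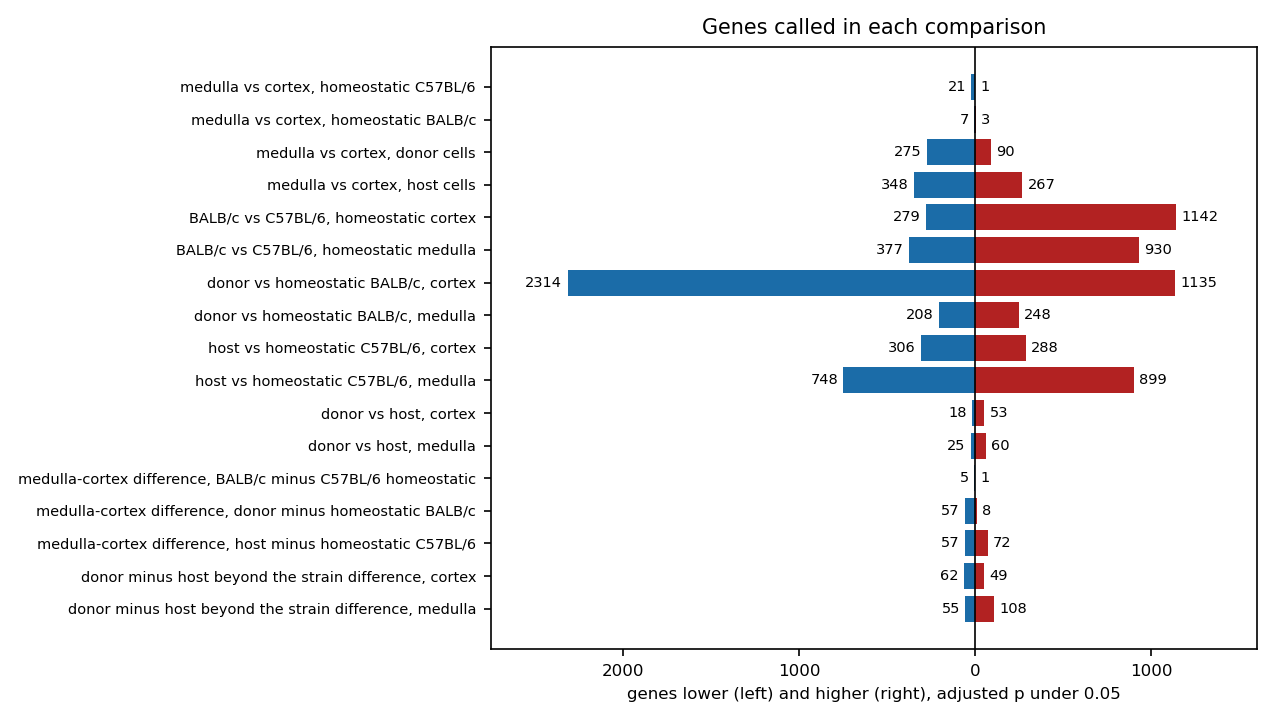
Number of genes higher and lower (bars, from 0) at adjusted p under 0.05 of 14346 genes in each of the 12 comparisons of groups and the 5 comparisons of differences. The bars run from 6 genes for the strain difference of the regions to 3449 for donor against homeostatic BALB/c cortex.

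Host cells of the graft were set against homeostatic C57BL/6 cells to see how cells of the recipient differ from those of a healthy kidney. Host cells of the cortex held little of the transcripts of resident macrophages and more natural killer and plasmacytoid dendritic cell transcripts. C1qc, which macrophages make, was at 7.40 ± 0.14 against 12.89 ± 0.08, difference -5.48 ± 0.25. Adgre1, which encodes F4/80, was at 6.65 ± 0.78 against 12.27 ± 0.19, difference -5.62 ± 0.41, and Mrc1, the mannose receptor, at 6.88 ± 0.52 against 11.79 ± 0.12, difference -4.90 ± 0.35. C3ar1, Csf1r and Cx3cr1 fell by 5.66 ± 0.29, 3.83 ± 0.25 and 3.46 ± 0.29. Gzmb was at 10.23 ± 1.97 against 6.95 ± 0.39, difference 3.29 ± 0.51, and Ncr1 at 8.70 ± 0.13 against 6.50 ± 0.59, difference 2.19 ± 0.44. Siglech, a receptor of plasmacytoid dendritic cells, rose by 2.69 ± 0.59. Host cortex replicate 3 stood apart, with Gzmb at 11.49, 11.25 and 7.96 on replicates 1, 2 and 3, against 6.68 to 7.52 on C57BL/6 cortex arrays, and plasmacytoid markers averaged 10.71, 9.58 and 8.17, against 8.03 to 8.25. Resident macrophage markers (11 of 16 lower, 11 over the list alone, median -2.62, adjusted p = 1.9e-30) fell. Rises were those of natural killer markers (3 of 6 higher, 3 over the list alone, median 1.60, adjusted p = 6.7e-06) and plasmacytoid dendritic cell markers (4 of 7 higher, 6 over the list alone, median 0.98, adjusted p = 1.8e-06). Leukocyte-wide genes had a median of -0.82 and epithelium-wide genes of 0.80.

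Other falls in host cortex that held with an estimated correlation were those of phagocytic and scavenger receptors (9 of 15 lower, 11 over the list alone, median -1.71, adjusted p = 2.3e-15), complement genes (2 higher and 5 lower of 9, 3 higher and 5 lower over the list alone, median -2.72, adjusted p = 2.1e-06) and MHC class II genes (6 of 10 lower, 9 over the list alone, median -1.43, adjusted p = 3.0e-12). So did those of pattern recognition receptors (6 of 14 lower, 10 over the list alone, median -1.52, adjusted p = 1.8e-11) and inflammatory cytokines and chemokines (6 of 19 lower, 7 over the list alone, median -0.16, adjusted p = 5.8e-06). Ccl3 and Il1b fell by 4.62 ± 0.75 and 3.84 ± 0.51. By the set test alone, interferon-gamma response genes (2 higher and 1 lower of 16, 4 higher and 1 lower over the list alone, median 0.85, adjusted p = 0.0021) were higher, but adjusted p = 0.17 with an estimated correlation. Iigp1 rose by 2.43 ± 0.56 and Ciita fell by 1.45 ± 0.29. Lower were type I interferon response genes (median -0.75, adjusted p = 6.7e-05), but adjusted p = 0.074 with an estimated correlation. Tubule lists on the higher side were proximal tubule (median 1.05, adjusted p = 1.8e-06) and collecting duct markers (median 0.67, adjusted p = 6.7e-05), but adjusted p = 0.11 and 0.091 with an estimated correlation. So were endothelial markers (median 0.15, adjusted p = 0.027), but adjusted p = 0.29 with an estimated correlation. In all, 594 genes passed, 288 higher and 306 lower; 19 lists were called, 11 also with an estimated correlation. The count became 345 and 356 without host cortex replicates 2 and 3. Siglech and Iigp1 lost their calls without host cortex replicate 2. Other settings gave 313 (groups alone) and 1402 (array weights, 788 higher and 614 lower).

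**Figure D3:**
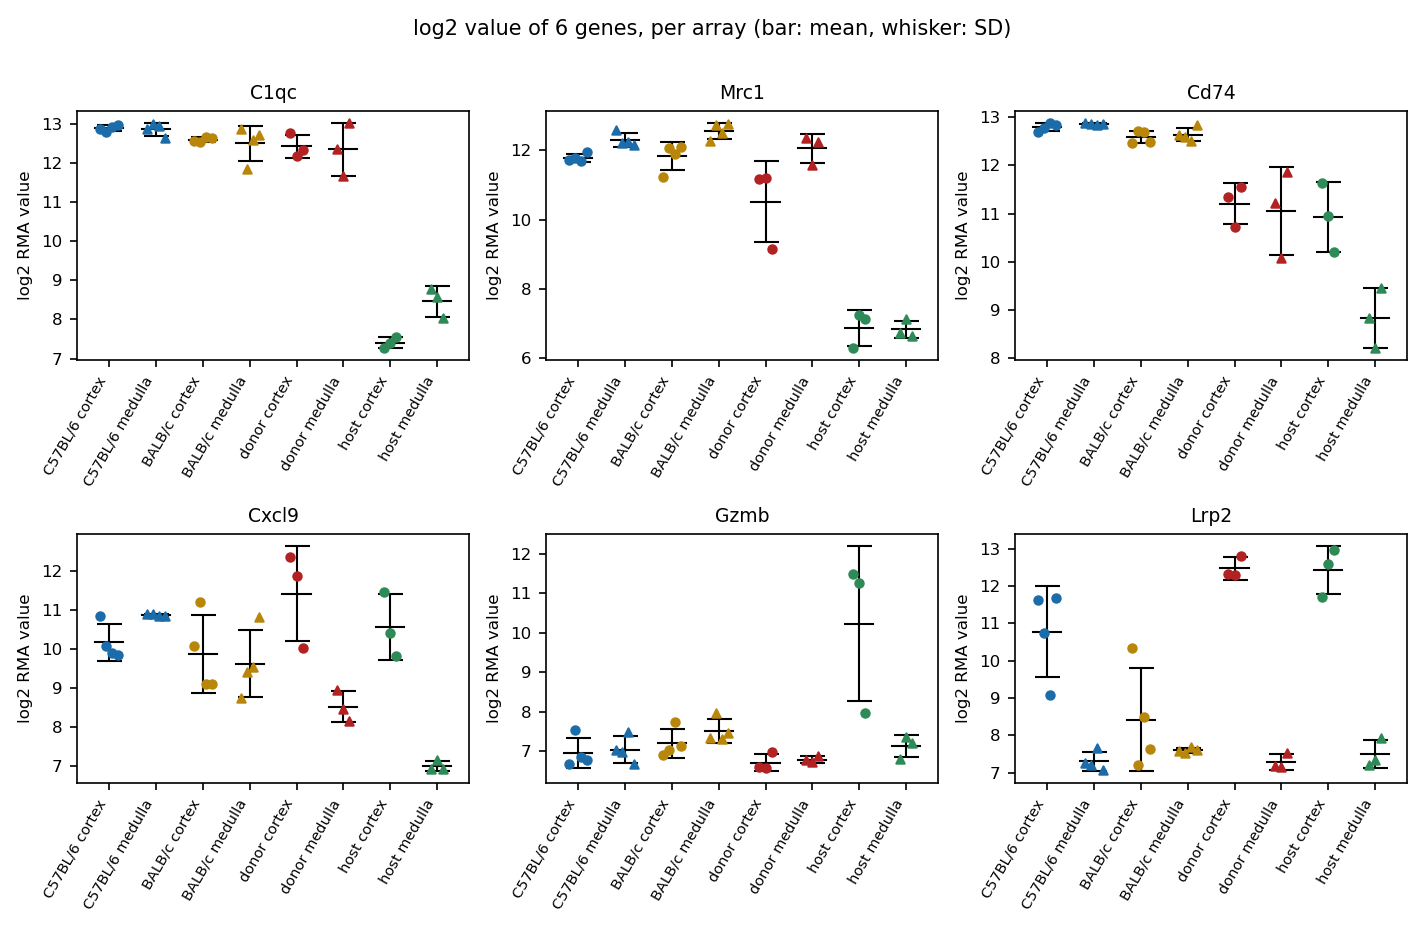
Log2 level (vertical axes) of C1qc, Mrc1, Cd74, Cxcl9, Gzmb and Lrp2 on each array in the 8 groups (horizontal axis); points are arrays, bars are group means and whiskers are SD. C1qc averaged 7.40 in host and 12.42 in donor cortex, and 8.46 in host and 12.34 in donor medulla.

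In the medulla, host cells fell in most lists of dendritic cells and macrophages and rose in collecting duct transcripts. Cd74 was at 8.83 ± 0.63 against 12.86 ± 0.02, difference -4.03 ± 0.33. Mrc1 was at 6.83 ± 0.26 against 12.30 ± 0.20, difference -5.47 ± 0.35, and C1qc at 8.46 ± 0.39 against 12.86 ± 0.16, difference -4.40 ± 0.25. Ccr2, Cd86 and Il1b differed by -4.83 ± 0.47, -5.71 ± 0.55 and -4.57 ± 0.51. The sort markers Ptprc, Itgax and H2-Ab1 differed by -3.12 ± 0.40, -3.43 ± 0.56 and -3.70 ± 0.40. Here 18 of 22 leukocyte-wide genes were lower, with a median of -2.87, and 13 of 14 epithelium-wide genes were higher, with a median of 2.34. Falls that held with an estimated correlation were those of MHC class II genes (10 of 10 lower, 10 over the list alone, median -2.84, adjusted p = 3.2e-21), type 2 conventional dendritic cell markers (7 of 7 lower, 7 over the list alone, median -2.93, adjusted p = 5.2e-11) and resident macrophage markers (11 of 16 lower, 11 over the list alone, median -2.51, adjusted p = 1.9e-19). So did those of type 1 conventional dendritic cell markers (5 of 12 lower, 5 over the list alone, median -1.21, adjusted p = 2.7e-07), complement genes (6 of 9 lower, 6 over the list alone, median -2.64, adjusted p = 4.6e-12) and phagocytic and scavenger receptors (10 of 15 lower, 12 over the list alone, median -2.26, adjusted p = 3.7e-17). The same holds for monocyte markers (median -2.83, adjusted p = 2.0e-05), chemokine receptors (median -1.02, adjusted p = 7.2e-06) and dendritic cell maturation genes (median -0.48, adjusted p = 1.2e-05).

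Lower in host medulla by the set test alone were interferon-gamma (median -1.03, adjusted p = 8.8e-05) and type I interferon response genes (median -0.80, adjusted p = 1.1e-04), but adjusted p = 0.072 each with an estimated correlation. Collecting duct markers (5 of 12 higher, 6 over the list alone, median 0.98, adjusted p = 5.8e-06) rose. Aqp2, the water channel of the collecting duct, rose by 1.62 ± 0.37. Loop of Henle and distal tubule markers (5 of 11 higher, 9 over the list alone, median 2.71, adjusted p = 1.3e-05) were higher by the set test, but adjusted p = 0.083 with an estimated correlation. Of the proximal tubule list, Gatm, the first enzyme of creatine synthesis, fell by 5.83 ± 0.31 while Aqp1, a water channel, rose by 3.55 ± 0.47, and the list was not called (adjusted p = 0.12). Slc5a3, the inositol transporter that hypertonic medium induces, rose by 4.45 ± 0.96. In all, 1647 genes passed, 899 higher and 748 lower; 21 lists were called, 13 also with an estimated correlation. Cortex and medulla shared 91 of the genes higher and 243 of those lower in host cells, against 18.1 if independent for those higher.

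Donor and host cells of the same grafts were compared to see how cells that came with the kidney differ from those of the recipient. In the cortex, donor cells held more macrophage and complement transcripts, and host cells more natural killer and plasmacytoid ones. C1qc was at 12.42 ± 0.30 against 7.40 ± 0.14, difference 5.02 ± 0.27, and C3ar1, the receptor of complement fragment C3a, at 11.97 ± 0.26 against 6.93 ± 0.48, difference 5.05 ± 0.31. Adgre1 and Mrc1 differed by 4.16 ± 0.43 and 3.63 ± 0.38, and Msr1, a scavenger receptor, by 3.68 ± 0.62. Gzmb was at 6.71 ± 0.22 against 10.23 ± 1.97, difference -3.53 ± 0.54, and Nkg7, a granule protein of cytotoxic cells, differed by -2.15 ± 0.47. Siglech and Ccr9, both carried by plasmacytoid dendritic cells, differed by -2.85 ± 0.63 and -3.16 ± 0.68, and Cd8a by -1.66 ± 0.38. Higher in donor cells were resident macrophage markers (7 of 16 higher, 9 over the list alone, median 1.52, adjusted p = 2.6e-33), complement genes (4 of 9 higher, 5 over the list alone, median 1.77, adjusted p = 4.7e-20) and phagocytic and scavenger receptors (3 of 15 higher, 8 over the list alone, median 0.88, adjusted p = 1.3e-13). Lower were natural killer markers (3 of 6 lower, 6 over the list alone, median -2.89, adjusted p = 4.0e-17), plasmacytoid dendritic cell markers (3 of 7 lower, 6 over the list alone, median -1.26, adjusted p = 1.1e-14) and T cell markers (1 of 11 lower, 3 over the list alone, median -1.01, adjusted p = 2.1e-08). Cell cycle genes (1 of 25 higher, 3 over the list alone, median 0.92, adjusted p = 1.1e-14) were higher. Leukocyte-wide genes had a median of -0.08 and epithelium-wide genes of -0.01.

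In graft cortex, 71 genes passed, 53 higher and 18 lower; 10 lists were called, 9 also with an estimated correlation. Nkg7 lost the call without donor cortex replicates 1, 2 or 3 or host cortex replicate 3, Siglech, Ccr9 and Cd8a without any one of 5 arrays. Other settings gave 41 (strict filter), 44 (renormalized), 4 (groups alone), 212 (array weights) and 0 by limma (fixed block) with 898 at an unadjusted p under 0.05.

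In the medulla, donor cells again held more macrophage and complement transcripts, and also more MHC class II transcripts. Mrc1 was at 12.06 ± 0.41 against 6.83 ± 0.26, difference 5.23 ± 0.38, and Apoe, the apolipoprotein of macrophages, at 12.47 ± 0.59 against 10.26 ± 0.10, difference 2.21 ± 0.23. C3ar1, C1qc and Adgre1 differed by 4.63 ± 0.31, 3.88 ± 0.27 and 3.87 ± 0.43. Cd74 differed by 2.22 ± 0.35 and Ccl2, which attracts monocytes, by 2.40 ± 0.55. Gatm was at 10.89 ± 1.14 against 6.06 ± 0.25, difference 4.83 ± 0.33, and Aqp4, a water channel of the collecting duct, differed by -1.34 ± 0.18. Higher were resident macrophage markers (8 of 16 higher, 12 over the list alone, median 1.91, adjusted p = 3.3e-41), complement genes (4 of 9 higher, 5 over the list alone, median 1.62, adjusted p = 1.4e-18) and MHC class II genes (3 of 10 higher, 5 over the list alone, median 0.76, adjusted p = 2.2e-07). So were phagocytic and scavenger receptors (median 1.14, adjusted p = 1.2e-22), inflammatory cytokines (median 0.21, adjusted p = 2.8e-06) and monocyte markers (median 0.43, adjusted p = 1.3e-04). Leukocyte-wide genes had a median of 0.63 with 3 of 22 higher, and epithelium-wide genes of -0.30. In all, 85 genes passed, 60 higher and 25 lower; 9 lists were called, 6 also with an estimated correlation. The count became 50, 134 and 53 without donor medulla replicates 1, 2 and 3. Ccl2 lost the call without any one of 5 arrays. Other settings gave 1 (groups alone), 221 (array weights) and 0 by limma (fixed block) with 969 at an unadjusted p under 0.05. Cortex and medulla shared 23 of the genes higher in donor cells, against 0.222 if independent, and 0 of those lower, against 0.0314.

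Donor and host cells differ in strain, so their difference was also set against that of homeostatic BALB/c and C57BL/6 cells. In the cortex macrophage and complement genes passed that test. The difference beyond the strain difference was 5.31 ± 0.35 for C1qc, 5.18 ± 0.41 for C3ar1, 4.74 ± 0.57 for Adgre1, 3.58 ± 0.50 for Mrc1, -3.77 ± 0.71 for Gzmb and -3.61 ± 0.84 for Siglech. The median difference of all genes was -0.12. Higher were resident macrophage markers (7 of 16 higher, 11 over the list alone, median 1.84 (1.97), adjusted p = 6.2e-16), complement genes (4 of 9 higher, 5 over the list alone, median 1.95 (2.08), adjusted p = 3.1e-09) and phagocytic receptors (3 higher and 1 lower of 15, 6 higher and 1 lower over the list alone, median 1.04 (1.17), adjusted p = 2.1e-05). Lower were natural killer markers (2 of 6 lower, 4 over the list alone, median -2.12 (-1.99), adjusted p = 4.4e-05) and plasmacytoid dendritic cell markers (2 of 7 lower, 6 over the list alone, median -1.47 (-1.34), adjusted p = 2.1e-05), but adjusted p = 0.13 with an estimated correlation for plasmacytoid markers. By the set test alone, cell cycle (median 1.05, adjusted p = 4.8e-07) and interferon-gamma genes (median 0.69, adjusted p = 0.008) were higher, but adjusted p = 0.22 and 0.28 with an estimated correlation. In all, 111 genes passed, 49 higher and 62 lower, at 2-fold or more 49 and 36; 15 lists were called (5 by fry), 4 also with an estimated correlation. The count became 39 without donor cortex replicate 1 to 539 without donor cortex replicate 3 over the 11 arrays that moved it, with 189 without BALB/c medulla replicate 1. Siglech lost the call without any one of 11 arrays. Other settings gave 244 (random block), 498 (no filter), 43 (strict filter, 34 higher and 9 lower), 43 (renormalized, 26 higher and 17 lower), 37 (groups alone, 29 higher and 8 lower) and 2046 (array weights).

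In the medulla the same test gave 4.96 ± 0.50 for Mrc1, 4.91 ± 0.41 for C3ar1, 4.24 ± 0.35 for C1qc, 4.04 ± 0.42 for Itgam, which encodes CD11b, 2.44 ± 0.47 for Cd74 and 2.60 ± 0.56 for H2-Ab1. All genes had a median of -0.19, leukocyte-wide genes of 1.34, 4 of 22 higher, and epithelium-wide genes of -1.1, 1 of 14 lower. Higher were resident macrophage markers (8 of 16 higher, 10 higher and 1 lower over the list alone, median 1.98 (2.17), adjusted p = 1.2e-17), MHC class II genes (4 of 10 higher, 8 over the list alone, median 1.71 (1.90), adjusted p = 1.9e-11) and complement genes (4 of 9 higher, 6 over the list alone, median 2.01 (2.19), adjusted p = 1.9e-11). So were phagocytic receptors (median 1.83, adjusted p = 2.0e-12), type 2 conventional dendritic cell markers (median 2.16, adjusted p = 6.0e-06) and monocyte markers (median 2.11, adjusted p = 1.4e-04). Dendritic cell maturation genes were called higher with a median of -0.01 and a mean of 0.41 (adjusted p = 0.033, adjusted p = 0.15 with an estimated correlation). In all, 163 genes passed, 108 higher and 55 lower; 18 lists were called (11 by fry), 6 also with an estimated correlation. The count became 104 and 98 without C57BL/6 medulla replicates 1 and 4 and 90 without donor medulla replicate 3. H2-Ab1 lost the call without donor medulla replicates 1 or 3 or host medulla replicates 2 or 3. Other settings gave 96 (groups alone) and 350 (array weights, 170 higher and 180 lower).

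Of the 31 lists tested in 17 contrasts, 3 were never called. The smallest adjusted p was 0.1 for the unfolded protein response, 0.17 for heme and iron handling and 0.22 for neutrophil markers. Erythroid and sex-linked genes had fewer than 3 members and were not tested as lists.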

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

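Tests chosen only after the result was seen were the strain difference of macrophage and complement genes, their fall beyond leukocyte-wide genes, natural killer genes in host cortex, leukocyte-wide genes between donor and host cells, their quartiles, and for the strain counts the rank correlation and the bounds for the quantile normalization and the left-out array. A sample far from the others of its group was found in 10 of 148 tests, where chance flags about 1 in 20 groups, or 7.4 of them. Homeostatic BALB/c medulla replicate 1 had a mean correlation of 0.766 with its group, against 0.832 to 0.841 for the others, and a mean of 8.54 for monocyte markers. The mean log2 level of interferon-gamma response genes was 9.35 on C57BL/6 medulla replicate 3, that of immediate early genes 9.67 on C57BL/6 medulla replicate 4 and that of pan dendritic cell markers 9.53 on C57BL/6 medulla replicate 1. MHC class I genes averaged 10.30 on BALB/c cortex replicate 1, B cell markers 8.09 on BALB/c cortex replicate 4 and endothelial markers 7.60 on C57BL/6 cortex replicate 1. Itgax was at 11.85 on BALB/c cortex replicate 2 and H2-Ab1 at 13.14 on C57BL/6 medulla replicate 2.

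Differences between groups in an effect, tested by an interaction term, were found for each of the 5 contrasts of differences, and mice were moved between the groups, or graft status drawn anew within a strain, to count other splits. The medulla-cortex difference of host cells differed from that of C57BL/6 cells for 129 genes, and that of donor from BALB/c cells for 65. In each case 1 of 35 splits, the real one, gave as many, a share under 0.05, not adjusted. The highest others gave 4 and 30. Between homeostatic BALB/c and C57BL/6 cells it differed for 6 genes, and 2 of 35 splits gave as many, the highest other 10, so chance is not excluded. The donor-host difference went beyond the strain difference for 111 genes in cortex and 163 in medulla, and 2 and 4 of 100 splits drawn gave as many, a share under 0.05. The highest other splits there gave 1885 and 601 genes, several times the real counts, and the reason was not tested.

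In the grafts, interferon-gamma and MHC class II genes were lower in host medulla than in host cortex (median -1.90 over 25 genes), and interferon-gamma genes were lower in donor medulla (-1.94). With tubule scores as covariates the host median was -2.60, but the median error rose from 0.45 to 1.03. Only 7 genes were called in host and 2 in donor cells. The proximal tubule score parts the regions, so this cannot decide on tubule RNA. Genes lower in donor medulla had a median within-group correlation of 0.428 with that score, against 0.0707 for all genes. Tubule RNA may account for part of those falls. The correlation was 0.199 for genes lower in host medulla, between the bounds set for and against. There tubule RNA cannot be told apart from a difference of the cells. Leukocyte-wide genes fell by part of the pattern, with medians of -1.35 in host and -0.53 in donor cells. Their lower quartile, -0.67 in donor cells, argues against a lower share of leukocyte RNA in the medulla samples as the whole cause there. The -2.28 in host cells does not, where their median fall was also close to that of MHC class II genes taken alone. How far the share adds cannot be told apart from a difference of the cells. A difference between the regions in the cells themselves, which the design names, stays open.

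Homeostatic cells of the strains differed for 1421 genes in cortex and 1307 in medulla. The BALB/c arrays spanned a narrower range, and across genes, which are not independent replicates, the strain difference fell with the mean level of the donor and host arrays of the region, which hold both strains (rank correlation -0.532 in cortex and -0.318 in medulla), so the range may account for part of the counts. A second quantile normalization, which makes the ranges equal, left 835 and 882 genes, which argues against range as the whole source. In the medulla 230 genes passed without BALB/c medulla replicate 1 and 285 to 521 without any 1 C57BL/6 array, so the part of that array cannot be told apart from that of losing a C57BL/6 array. Sequence differences between strains under the probes were not tested, and the strain itself stays open.

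The 22 macrophage and complement genes were lower in host than in homeostatic C57BL/6 cells (median -2.34 in cortex and -2.32 in medulla) and lower than in donor cells of the same grafts (donor minus host 1.07 and 1.60). Between the homeostatic strains their median difference was -0.12 in cortex and -0.24 in medulla, which argues against strain as the source of the donor-host difference. In the medulla leukocyte-wide genes had a median of -2.87 against homeostatic cells, so a lower share of leukocyte RNA in the host samples may account for that fall, and of 0.63 between donor and host cells, where the share cannot be told apart from a difference of the cells. In the cortex their median between donor and host cells was -0.078, which argues against such a share as the source of that difference; against homeostatic cells natural killer genes rose (median 1.60, lower quartile 0.86), which argues against it as the only cause. How far it adds to the fall there cannot be told apart from a difference between recipient and resident cells, which stays open, as leukocyte-wide genes had a median of -0.82 and macrophage and complement genes lay -1.51 from it with overlapping quartiles (-0.09 against -1.05).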

How the results depend on the processing

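The array weights, and the fits without BALB/c medulla replicate 1 of comparisons it is not part of, were chosen after seeing the data. All 155 named gene results kept their sign under every alternative. The call held under all for 65 and was lost under at least 1 for 90. These include 58 with a fixed block, 62 with the groups alone, 12 renormalized and 0 with a random block. Of the 205 list calls, 67 held with an estimated correlation, 135 with fry, 184 after quantile normalization, 189 without the filter, 184 with array weights and 193 without BALB/c medulla replicate 1, and 0 turned. With mouse as a block 202 held, all but the 3 named with the medulla-cortex comparisons of the grafts. A strict filter tests fewer genes and a fit of only the groups compared has fewer arrays for the spread; for other changes the cause was not tested. Genes left out as dim were not tested and are not shown to be absent.

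Below, region stands for medulla against cortex, strain for BALB/c against C57BL/6, donor and host for each against its homeostatic strain, donor-host for donor against host, and beyond-strain for that difference beyond the strain difference; a count changed when it moved by over 1.5 times. Mouse as a random block changed 4 of 17 counts, to 38 for C57BL/6 region, 40 for BALB/c region, 105 for donor minus BALB/c region and 244 for beyond-strain cortex. Mouse as a fixed block, run where the groups share mice, changed 9 of 9 counts, to 1 for C57BL/6 region, 0 for BALB/c region, 69 for donor region, 64 for host region, 0 for donor-host cortex, 0 for donor-host medulla, 0 for BALB/c minus C57BL/6 region, 27 for donor minus BALB/c region and 84 for host minus C57BL/6 region, where limma's 0 came with 655, 898, 969 and 797 genes at an unadjusted p under 0.05. Testing all genes without the filter on dim ones changed 6 of 17 counts, to 3897 for strain cortex, 3485 for strain medulla, 6427 for donor cortex, 997 for donor medulla, 0 for BALB/c minus C57BL/6 region and 498 for beyond-strain cortex, where limma's 0 came with 768 genes at an unadjusted p under 0.05. A strict filter on dim genes changed 10 of 17 counts, to 16 for BALB/c region, 234 for donor region, 398 for host region, 351 for strain cortex, 372 for strain medulla, 1669 for donor cortex, 41 for donor-host cortex, 30 for donor minus BALB/c region, 80 for host minus C57BL/6 region and 43 for beyond-strain cortex. A second quantile normalization changed 4 of 17 counts, to 40 for BALB/c region, 835 for strain cortex, 44 for donor-host cortex and 43 for beyond-strain cortex. A variance trend with robust estimates changed 1 of 17 counts, to 0 for BALB/c minus C57BL/6 region, where limma's 0 came with 611 genes at an unadjusted p under 0.05. A fit of only the groups compared changed 14 of 17 counts, to 5 for C57BL/6 region, 1 for BALB/c region, 188 for donor region, 135 for host region, 661 for strain cortex, 110 for strain medulla, 773 for donor cortex, 4 for donor medulla, 313 for host cortex, 4 for donor-host cortex, 1 for donor-host medulla, 3 for BALB/c minus C57BL/6 region, 37 for beyond-strain cortex and 96 for beyond-strain medulla. Array weights changed 10 of 17 counts, to 100 for C57BL/6 region, 1796 for donor region, 2702 for strain cortex, 5650 for donor cortex, 1402 for host cortex, 212 for donor-host cortex, 221 for donor-host medulla, 378 for host minus C57BL/6 region, 2046 for beyond-strain cortex and 350 for beyond-strain medulla. Of comparisons that do not hold BALB/c medulla replicate 1, leaving it out moved only beyond-strain cortex, to 189. The mean of a gene's probesets in place of the brightest changed none of the 17. Leaving out 1 array at a time gave 6 to 55 for C57BL/6 region, 8 to 29 for BALB/c region, 249 to 392 for donor region, 430 to 642 for host region, 504 to 1784 for strain cortex, 230 to 2353 for strain medulla, 1500 to 4357 for donor cortex, 60 to 1087 for donor medulla, 345 to 872 for host cortex, 1206 to 1787 for host medulla, 53 to 103 for donor-host cortex, 50 to 134 for donor-host medulla, 0 to 11 for BALB/c minus C57BL/6 region, 46 to 111 for donor minus BALB/c region, 85 to 187 for host minus C57BL/6 region, 39 to 539 for beyond-strain cortex and 90 to 201 for beyond-strain medulla.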

Other observations

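Of the tests in this part, those of monocyte genes in host cells were chosen only after the result was seen; the tests of natural killer transcripts and of the splits were set before. Lists not described above for these cells also moved in host cells against homeostatic C57BL/6 cells. In the cortex the falls of B cell markers (5 of 10 lower, 8 over the list alone, median -1.15, adjusted p = 4.7e-10) and chemokine receptors (1 higher and 3 lower of 10, 1 higher and 3 lower over the list alone, median -0.74, adjusted p = 0.0019) held with an estimated correlation. Bank1, a scaffold of B cell receptor signalling, and Fcer2a, which encodes CD23, fell by 2.85 ± 0.60 and 1.61 ± 0.33, while Ccr9 of the chemokine receptors rose by 2.49 ± 0.64. Immediate early genes, which rise when tissue is dissociated, were lower by the set test in cortex (median -0.57, adjusted p = 8.6e-05), but adjusted p = 0.099 with an estimated correlation. Nfkbiz, a regulator of NF-kappaB, fell by 1.58 ± 0.35 and Dusp1, a phosphatase of MAP kinases, by 1.22 ± 0.28. Cadm1, an adhesion protein of type 1 conventional dendritic cells, fell by 2.53 ± 0.23 in host cortex and by 2.27 ± 0.23 in host medulla, and Clec9a, their receptor of dead cells, by 4.84 ± 0.91 in host medulla. Nfkbiz lost the call without host cortex replicate 3, Dusp1 without host cortex replicate 1, and Ccr9 without C57BL/6 cortex replicates 1 or 2 or host cortex replicates 1 or 2.

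In host medulla genes of MHC class I presentation fell (4 of 11 lower, 5 over the list alone, median -0.54, adjusted p = 2.0e-05), a call that held with an estimated correlation. Tap1, the peptide transporter, fell by 1.80 ± 0.36 and B2m, the light chain of class I, by 0.54 ± 0.12, where leukocyte-wide genes had a median of -2.87. In donor medulla against homeostatic BALB/c medulla Psmb8, a subunit of the immunoproteasome, fell by 1.44 ± 0.32, a call lost without donor medulla replicates 2 or 3 or BALB/c medulla replicate 1.

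Natural killer transcripts as the companion of the interferon-gamma response in graft cortex were tested as a hypothesis. Natural killer genes had a median of -0.47 in donor cortex against homeostatic BALB/c cortex, where interferon-gamma genes had a median of 1.47, which argues against natural killer RNA inside the donor samples as the source of that rise. Over the 12 graft arrays the within-group correlation of the scores of both lists was 0.654, but these arrays come from 3 mice and are not independent, so that for host cells the hypothesis cannot be told apart from shared differences between mice.

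That host cells lacked macrophage transcripts because they had newly arrived from the blood was tested with monocyte markers, which should then stay or rise. Their median against homeostatic C57BL/6 cells was -0.46 in cortex and -2.83 in medulla. Leukocyte-wide genes fell alongside, with medians of -0.82 and -2.87, so new arrival and a lower share of leukocyte RNA cannot be told apart from these values.

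Each count was set against other splits of the same arrays into groups of the same sizes. Only 1 of 35 splits, the real one, gave as many genes for the next comparisons. These shares under 0.05 are not adjusted over comparisons. The strains gave 1421 genes in cortex against 35 in the highest other split, and 1307 in medulla against 15. Donor against homeostatic cortex gave 3449 against 1632. Host against homeostatic cells gave 594 against 215 in cortex and 1647 against 471 in medulla. For these last 3 that split still parted graft from homeostatic arrays but for 1 array. In C57BL/6 kidneys, where a mouse gave both regions, medulla against cortex gave 22 genes against 1 in the highest of the 34 others, but the 8 splits that part all pairs, with 0 in the highest other, are too few for a share under 0.05. In homeostatic BALB/c cells 9 of 35 splits gave at least the 10 genes of medulla against cortex. So did 4 of the 8 splits that part all pairs, where the highest other gave 23, and chance is not excluded. The highest of all gave 337 genes, and the reason was not tested. For donor against homeostatic medulla 3 of 35 splits gave at least 456 genes, the highest other 966, and chance is not excluded. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. Medulla against cortex gave 365 genes against 30 in the highest other split in donor cells and 615 against 45 in host cells. Donor against host gave 71 against 57 in cortex and 85 against 45 in medulla. Among the 4 splits that part all pairs the highest other gave 3, 5, 1 and 3 genes, in the same order.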
